A study of Arabidopsis thaliana with 9 samples.

How the data were processed

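The series holds 9 RNA-seq libraries of whole Arabidopsis thaliana seedlings, 3 of wild type and 3 of each of 2 lines, and their groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a Takara MiniBEST plant kit and libraries were made with an NEBNext Ultra RNA kit. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.1.10, DESeq2 1.26.0 and the TAIR10 genome were used. The deposited table gives TPM, made by the authors, for 27655 genes, with Araport11 in its gene names. The read counter and its strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and close copies can exchange reads.

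Each library's TPM sums to 1000000, so a large change in abundant genes shifts the values of all others. The 100 most abundant genes held 38.4% to 38.7% of the TPM in wild type, 34.6% to 36.4% in G34R and 33.3% to 33.5% in G34W, and organelle genes held 0.093% to 0.138%. Reads were recovered from the TPM by seeking, for each gene, a length at which all of its values are whole reads, with its span in the reference table of the TAIR10.1 assembly, introns included, tried before other lengths. Whole reads within a relative tolerance of 1e-06 were found for all 23235 genes above 0 in at least 1 library (100%), and the span served for 99.4% of them. The TPM of most genes thus match reads divided by a span with introns. Genes with long introns get lower TPM at the same number of reads, which bears on TPM filters and on log2(TPM + 1). On simulated data the recovery gave every read count exactly for 98.3% of 22095 genes. The recovered totals were 12895442 to 14739554 reads per library, and 3 reads in a gene of 1 kb correspond to 0.422 to 0.495 TPM. Floors of 3 reads cover counting error only.

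Gene symbols came from the gene lists described below and otherwise from that reference table, and 10405 of the 27655 loci had one. Loci without a symbol could not be named among the largest changes by the naming rule. The reference table holds 27445 of the loci (99.24%), and the 210 others are organelle loci. Its assembly differs from TAIR10 by name, so no positions are given from it, and it served for names, gene spans, strands and the order of neighbouring genes. Replicates differed by more than sampling noise, with chi-square per degree of freedom of 1.77 to 2.0 in wild type, 2.51 to 5.31 in G34R and 1.81 to 1.95 in G34W, so none was taken for a repeat of another. Pearson correlations of log2(TPM + 1) were 0.99 to 0.992 within groups, 0.955 to 0.961 between wild type and G34R, 0.96 to 0.962 between wild type and G34W and 0.976 to 0.979 between the lines. The first 3 principal components held 58.7%, 21.1% and 4.3% of the variance. On the third, G34R replicates 1, 2 and 3 lay at 17.05, -1.07 and -18.24, and the other libraries from -3.63 to 4.07. The labels do not say whether replicates were separate plantings, so p-values measure only the spread between these samples, which may be technical.

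Genes with a mean of at least 1 TPM over the 9 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 linear model over the 3 groups, moderated variances with a trend, and two-sided tests adjusted by the Benjamini-Hochberg method at 0.05. The design fixed a count-based test only for the case that the table held raw counts, which it did not. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were measured, adjusted over the lists of a comparison, and again with an estimated correlation. The lists covered H3.3 genes, H3.1 genes, H3K36 and H3K4 methylation, Polycomb, H3 chaperones, floral repressors, floral promoters and integrators, floral organ identity, the autonomous pathway, the morning and the evening clock, salicylic acid, jasmonate, abscisic acid with drought and cold, heat shock, rapid stress, photosynthesis, iron, phosphate, mitosis and replication, DNA damage, seed maturation, flavonoids, glucosinolates, auxin, DNA methylation, senescence, root hairs, root endodermis and tip, the stomatal lineage and reference genes, 31 in all with 416 loci. Floral organ identity had 1 measured member and was not tested as a list.

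The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule HTR4, HTR5, HTR8, FLC, FT and SOC1 were always named. To these came, for each comparison with wild type, the 8 genes with the largest rise and the 8 with the largest fall among genes with a symbol, a mean of at least 5 TPM, an adjusted p under 0.05 and groups that did not overlap, with 5 and 5 between the lines, and up to 4 called members of each list by smallest adjusted p in either comparison with wild type, or the 1 member with the smallest p where none was called. This gave 141 genes. Overlap and correlation between the 2 comparisons with wild type were set beside 100 simulated draws of unchanged groups. In each draw all libraries were simulated, and both comparisons shared the simulated wild-type libraries.

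The steps were tested on simulated data in which 50 genes each were changed by 1.25, 1.5, 2 and 4-fold in a copy of the comparison of G34R with wild type. With changed genes of any abundance, 24%, 60%, 78% and 98% of them were recovered among 18095 genes, and 42 of 172 calls were false (24.4%), against 5 of 130 with median-ratio scaling. A second draw, added after that result was seen, took changed genes from 2 to 500 TPM only and recovered 18%, 36%, 90% and 100% among 18119 genes with 8 false calls of 130 (6.2%). In the real data genes above 500 TPM changed too, LHCB1.4 among them, so the 6.2% does not carry over to the main fit. No gene was called in the unchanged simulated group, and 0 of 30 random lists were called. The reads of each gene were drawn independently of other genes, so these lists did not test the preset inter-gene correlation. The alternatives were pseudocount 0.1, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, organelle genes left out, a replicate block, array quality weights, robust moderation, only the 2 groups compared, a 2-fold threshold, an estimated correlation and each library left out in turn. Fits of limma-voom to the recovered reads, with library totals or median-ratio sizes, were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.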

Results

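Messenger RNA was profiled in 10-day-old Arabidopsis thaliana seedlings kept at 22 °C with 16 h of light and 8 h of dark a day. The 9 libraries fell into 3 groups of 3: wild type of the Col accession, and lines labelled h3.3ko;HTR5 G34R and h3.3ko;HTR5 G34W, here called G34R and G34W. H3.3 is the histone H3 variant that is deposited outside DNA replication, mostly over transcribed genes, and HTR4, HTR5 and HTR8 are the genes that encode it. By the usual notation, the labels name a glycine of the HTR5 protein exchanged for arginine in G34R and for tryptophan in G34W, in a background marked h3.3ko. A line of that background with an unchanged HTR5 was not analysed here, so the substitution and the background cannot be separated. Reads recovered from the deposited TPM came to 12895442 to 14012397 per wild-type library, 14258184 to 14739554 in G34R and 13569961 to 14322281 in G34W. Between 21134 and 21563 genes were above 0 in a library, and 18544 genes with a mean of at least 1 TPM were tested. TPM are given as mean ± SD and log2 fold changes as value ± SE, with n = 3 libraries per group. The fold changes are on the log2(TPM + 1) scale, which understates the change of weakly expressed genes.

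The H3.3 genes separated the lines from the wild type in every library. HTR8 was at 214, 207 and 210 TPM in the 3 wild-type libraries, at 5.07, 3.92 and 5.86 TPM in G34R and at 6.69, 4.65 and 5.24 TPM in G34W. HTR4 was at 438, 408 and 408 TPM in wild type, at 132, 135 and 137 TPM in G34R and at 161, 152 and 165 TPM in G34W. HTR5 was at 331, 335 and 334 TPM in wild type, at 360, 353 and 357 TPM in G34R and at 382, 368 and 390 TPM in G34W. HTR8 fell by 5.16 ± 0.12 on the log2 scale in G34R (adjusted p = 4.33e-15) and fell by 5.03 ± 0.12 in G34W (adjusted p = 8.42e-15). HTR4 fell by 1.62 ± 0.04 in G34R (adjusted p = 1.31e-14) and fell by 1.39 ± 0.04 in G34W (adjusted p = 9.8e-14). HTR5 was 0.10 ± 0.03 higher in G34R (adjusted p = 0.013) and 0.19 ± 0.03 higher in G34W (adjusted p = 6.43e-05), and with median-ratio scaling of the libraries these values turned to -0.03 in both lines. In the list of the 3 H3.3 genes, 2 thus fell and 1 rose in each line, with a list test of adjusted p = 0.00729 in G34R and adjusted p = 0.0071 in G34W. Neither call held, with adjusted p = 0.174 with an estimated correlation in G34R and 0.167 in G34W. The list test bears on the 3 genes as a set and not on the change of each gene. The 3 genes encode the same protein, HTR4 and HTR5 are neighbours in the TAIR10.1 annotation, and reads could be exchanged between such copies, so the split of reads among them is uncertain.

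**Figure D1:**
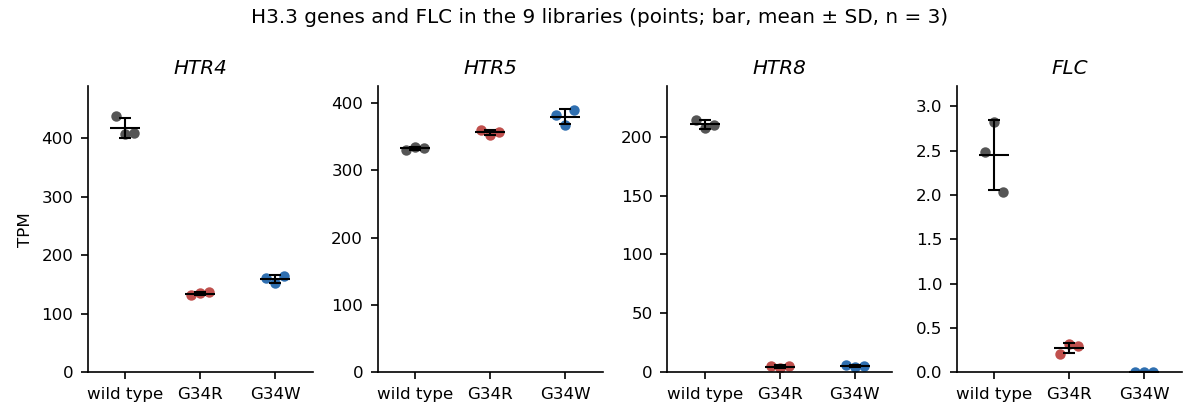
TPM of HTR4, HTR5, HTR8 and FLC (vertical axes, each starting at 0) in the 3 libraries of wild type, G34R and G34W (points), with the mean and SD of each group (bars, n = 3). HTR8 lay at 207 TPM or more in wild type and at 6.69 TPM or less in both lines, and FLC was listed at 0 in the 3 G34W libraries.

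Flowering-time genes differed between the groups as well. FLC, the MADS-box repressor of flowering, was listed at 2.49, 2.83 and 2.04 TPM in wild type (94, 104 and 81 reads), at 0.209, 0.316 and 0.294 TPM in G34R (9, 13 and 12 reads) and at 0 in the 3 G34W libraries. Its mean level lay under the filter of the main test. For FLC 3 reads were 0.0762 TPM on average in G34W, against 0.422 to 0.495 TPM in a gene of 1 kb. Its low TPM thus reflects gene length too. Without the filter FLC fell by 1.43 ± 0.11 on the log2 scale in G34R (adjusted p = 1.13e-06), and with a floor of 3 reads in each G34W library it was at least 32.2-fold lower in G34W than in wild type and at least 3.58-fold lower than in G34R. These floors cover counting error only, and 4420 genes of the table were listed at 0 in all 9 libraries, among them the jasmonate regulator MYC2, so that a 0 can also be a failed estimate. FT, the mobile flowering signal, was at 0.380 ± 0.199 TPM in wild type, 0.482 ± 0.272 TPM in G34R and 3.44 ± 0.876 TPM in G34W. It rose by 1.68 ± 0.21 in G34W (adjusted p = 5e-06), while the G34R value of 0.10 ± 0.21 did not pass the test (adjusted p = 0.726). FT rested on 3, 6 and 10 reads in wild type, 7, 5 and 14 in G34R and 67, 67 and 42 in G34W. SOC1, which integrates flowering signals, rose from 15.4 ± 1.02 TPM to 24.7 ± 3.02 TPM in G34R (0.64 ± 0.09, adjusted p = 1.46e-05) and to 24.2 ± 1.49 TPM in G34W (0.62 ± 0.09, adjusted p = 1.84e-05).

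The comparison of G34R with wild type asked which transcripts differ in the line with arginine. The named genes with the largest changes had a symbol, a mean of at least 5 TPM and groups that did not overlap. CRA1, a 12S seed storage protein, went from 0.304 ± 0.203 to 19.8 ± 1.80 TPM (4.01 ± 0.15, adjusted p = 1.64e-12), CYP82C4, a cytochrome P450 of iron-deficient roots, from 4.04 ± 0.634 to 57.2 ± 4.08 TPM (3.53 ± 0.10, adjusted p = 6.36e-14) and FER1, an iron-storing ferritin, from 88.0 ± 3.08 to 522 ± 5.43 TPM (2.56 ± 0.03, adjusted p = 7.6e-18). The lipid-transfer protein gene LTP3 rose by 3.503, the nicotianamine synthase gene NAS2 by 3.34, the linker histone gene HIS1-3 by 2.72, the glucosinolate chain-elongation gene MAM3 by 2.71 and the glutathione transferase gene GSTU25 by 2.43, each with an SE of at most 0.15. The largest falls after HTR8 were those of ZAT10, a stress-induced zinc-finger repressor, from 33.8 ± 4.43 to 2.95 ± 0.849 TPM (-3.15 ± 0.16, adjusted p = 9.13e-11), and of the transcription factor genes WRKY40 (-2.95 ± 0.18) and WRKY70 (-2.69 ± 0.12). RLP19, a receptor-like protein gene, had a change of -2.54, CAF1a, a deadenylase gene, of -2.51, IAA29, an auxin-response repressor gene, of -2.48, and BT1, which encodes a BTB and TAZ domain protein, of -2.47.

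Most root markers rose in G34R. All 8 root hair markers rose, with a median of 1.42, which is 1.32 above the median of all tested genes (adjusted p = 0.000829, and adjusted p = 0.138 with an estimated correlation). Among them the wall protein genes PRP3 and PRP1 rose by 1.83 ± 0.11 and 1.89 ± 0.18 and the expansin genes EXP7 and EXP18 by 1.43 ± 0.13 and 1.53 ± 0.16. Of the 8 measured root endodermis and root tip markers 6 rose, 1 fell and 1 did not pass the test (adjusted p = 0.0257, and adjusted p = 0.173 with an estimated correlation). CASP1, which builds the Casparian strip of the endodermis, went from 19.7 ± 0.997 to 53.9 ± 2.62 TPM, and CASP2, CASP4 and CASP5 rose by 1.03, 0.85 and 2.02. In the iron deficiency list 8 of 13 genes rose, 2 fell and 3 did not pass, with a list test of adjusted p = 0.181. The iron transporter gene IRT1 went from 23.5 ± 0.986 to 126 ± 4.95 TPM, and the iron reductase gene FRO2, the regulator gene FIT and the coumarin synthesis gene F6H1 rose by 1.81, 1.28 and 1.49. Phosphate starvation genes gave 1 rise, 4 falls and 4 without a call among 9 (adjusted p = 0.0772): the phosphate transporter gene PHT1;1 rose by 1.55, and the lipid-remodelling genes SQD1 and MGD2 and the sensor gene SPX1 had changes of -0.71, -0.91 and -0.48.

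Only the rapid touch, wound and stress list was called among the stress-response lists in G34R, and its genes mostly fell. Of the 17 measured genes of the rapid touch, wound and stress list 13 fell, 1 rose and 3 did not pass, with a median of -0.65, and the call held in both forms of the list test (adjusted p = 3.61e-08, and adjusted p = 0.0182 with an estimated correlation). The ethylene-response factor gene ERF104, the zinc-finger gene SZF1 and the MAP kinase gene MPK3 had changes of -1.71 ± 0.08, -1.45 ± 0.07 and -0.65 ± 0.05. Of 10 salicylic acid and defence genes 6 fell, 3 rose and 1 did not pass (adjusted p = 0.0628, and 0.0431 without G34R replicate 1). CBP60G and EDS1, regulators of that pathway, had changes of -1.64 and -0.62, and the defence gene PR5 of -0.78. In the abscisic acid, drought and cold list 15 of 21 genes rose, 3 fell and 3 did not pass (adjusted p = 0.0628, and 0.0486 without G34R replicate 3). There KIN1, a cold-induced gene with the near-identical copy KIN2, rose by 2.12 ± 0.24 and the dehydrin gene RAB18 by 0.44 ± 0.05, RD29B had a change of -0.69 ± 0.09, and P5CS1 and RD22 were at 0.11 (adjusted p = 0.0805) and 0.05 (adjusted p = 0.25). Jasmonate genes gave 7 rises, 5 falls and 2 without a call among 14, and their median of 0.35 and mean of 0.24 were positive while the list test pointed down (adjusted p = 0.979). The storage protein gene VSP1 of that list rose by 1.83, and the synthesis genes AOC1, AOC2 and AOS had changes of -1.13, -0.43 and -0.25, with AOC1 and AOC2 close copies. Heat shock genes gave 2 rises, 5 falls and 2 without a call among 9 (adjusted p = 0.275). The chaperone gene HSP90.1 was up by 0.99, the coactivator gene MBF1C up by 0.56, HSP70 at -0.61 and the factor gene HSFA7A at -0.41.

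More photosynthesis genes and morning clock genes fell than rose in G34R. Of 36 nuclear photosynthesis genes 20 fell, 4 rose and 12 did not pass (adjusted p = 1.02e-07, and adjusted p = 0.289 with an estimated correlation). The light-harvesting gene LHCB1.4 went from 5374 ± 65.4 to 2692 ± 145 TPM, and LHCB2.3, LHCB2.2 and LHCB2.1 had changes of -0.60, -0.41 and -0.41, although reads may be shared among these near-identical copies. The list's median was -0.08 as deposited, -0.21 with median-ratio scaling, where 30 genes fell and 0 rose, and 0.02 with quantile normalization, which ended the call (adjusted p = 0.8, within a range of 1.72e-13 to 0.8 over all alternatives). Of 9 morning clock genes 5 fell, 0 rose and 4 did not pass (adjusted p = 5.15e-05, and adjusted p = 0.238 with an estimated correlation). LHY and CCA1 of the core oscillator were at -0.71 ± 0.05 and -0.59 ± 0.04, and the coactivator genes LNK1 and LNK2 at -0.55 and -0.42. Of 5 measured evening clock genes 3 rose, 0 fell and 2 did not pass (adjusted p = 0.286), namely TOC1 by 0.71, LUX by 0.81 and ELF4 by 0.996.

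Among chromatin genes in G34R, the 5 H3.1 genes, which encode the replication-coupled H3, all rose (adjusted p = 0.00729, and adjusted p = 0.166 with an estimated correlation). HTR2 went from 109 ± 1.96 to 185 ± 9.41 TPM, and HTR1, HTR9 and HTR13 rose by 0.39, 0.43 and 0.44, with the reservation that these copies are nearly identical. The list of genes that write, erase or read H3K36 and H3K4 methylation has 12 members, among them REF6, a gene of H3K27 demethylation. In this list 2 rose, 2 fell and 8 did not pass (adjusted p = 0.275), and 2 rose and 6 fell with median-ratio scaling. The demethylase gene JMJ30 rose by 0.84 ± 0.15 and the reader gene MRG1 by 0.37 ± 0.07, the H3K27 demethylase gene REF6 had a change of -0.38 ± 0.11, and the H3K36 methyltransferase gene SDG8 had a change of -0.45 ± 0.14 that missed the threshold without wild type replicate 3 or G34R replicate 1 (adjusted p up to 0.0859). Polycomb genes gave 1 rise, 0 falls and 6 without a call among 7, with a median of 0.05 that became -0.07 with median-ratio scaling and a list test that pointed down (adjusted p = 0.993). MSI1 was the gene that rose, by 0.27, and median-ratio scaling ended its call (adjusted p = 0.0518), while SWN, EMF2 and CLF were at 0.13, -0.06 and 0.01. None of the 8 H3 chaperone genes passed (adjusted p = 0.44), and ASF1B, HIRA and FAS2 were at 0.08, 0.11 and 0.09, each under 0 with median-ratio scaling, where 2 genes of the list fell. Among 6 DNA methylation genes 0 rose, 1 fell and 5 did not pass (adjusted p = 0.499), the fall being IBM1, an H3K9 demethylase gene, at -0.44, while DDM1 and ROS1 were at 0.16 and -0.07. That list's median of 0.03 turned to -0.09 with median-ratio scaling.

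Among the other flowering genes SPL4 rose and FLM and SVP fell in G34R. Of 4 measured floral repressors 2 fell, 1 rose and 1 did not pass (adjusted p = 0.286). FLM was at -0.47, SVP at -0.27 and MAF2 at 0.29, whose call was lost without G34R replicate 2 (adjusted p = 0.0683) and with median-ratio scaling (adjusted p = 0.141). Of 4 floral promoters and integrators 2 rose, 0 fell and 2 did not pass (adjusted p = 0.468), and besides SOC1 the riser was SPL4 at 1.04, while SPL3 was at -0.09. SEP3, the 1 measured floral organ identity gene, was at 1.51 ± 0.369 and 1.59 ± 0.270 TPM (0.05, adjusted p = 0.82), and its sign turned with median-ratio scaling. Of 6 autonomous pathway genes 0 rose, 1 fell and 5 did not pass (adjusted p = 0.275). The fall was that of FVE at -0.21, which missed the threshold without wild type replicate 1 or G34R replicate 1 or 3 (adjusted p up to 0.0867), and LD, FLD and FY were at 0.06, 0.04 and -0.10.

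Growth and metabolism lists completed the comparison. Auxin response genes gave 4 rises, 8 falls and 2 without a call among 14 (adjusted p = 0.0184, and adjusted p = 0.166 with an estimated correlation). IAA1 was at -1.23, IAA2 at -0.50 and the auxin-conjugating enzyme gene GH3.3 at 0.56. Senescence and carbon starvation genes gave 3 rises, 5 falls and 1 without a call among 9 (adjusted p = 0.0184, and adjusted p = 0.166 with an estimated correlation). DIN1 was at -1.62, NAP at -0.90, DIN6 at -0.57 and SAG21 at 0.74. Flavonoid genes gave 1 rise, 6 falls and 4 without a call among 11 (adjusted p = 0.0184, and adjusted p = 0.174 with an estimated correlation). The anthocyanin glucosyltransferase gene UGT75C1 was at -0.93, the reductase gene DFR at -0.36 (adjusted p up to 0.101 without wild type replicate 2 or G34R replicate 1), and TT4 and FLS1 at -0.08 and -0.13 without a call. Glucosinolate genes gave 8 rises, 6 falls and 6 without a call among 20, and the list test pointed down (adjusted p = 0.642) against a median of 0.05, which became -0.08 with median-ratio scaling, and a mean of 0.10. The regulator genes MYB34 and MYB28 were at 1.43 and -1.10 and CYP83B1 at -0.09. Mitosis and replication genes gave 10 rises, 0 falls and 14 without a call among 24 (adjusted p = 0.44), and 6 rises and 2 falls with median-ratio scaling. There CDKB1;1 rose by 0.89, CDC20.2 was at 0.38 (adjusted p up to 0.0615 without wild type replicate 2 or G34R replicate 3, and 0.0575 with median-ratio scaling), and PCNA1 and CDKB2;1 were at -0.07 and 0.19 without a call. DNA damage genes gave 5 rises, 0 falls and 7 without a call among 12 (adjusted p = 0.945), and 2 rises and 2 falls with median-ratio scaling. RAD17 was at 0.59, PARP2 at 0.56, a call that quantile normalization ended (adjusted p = 0.0577), SOG1 at 0.36, a call that median-ratio scaling ended (adjusted p = 0.0669), and TSO2 at -0.06. Seed maturation genes gave 3 rises, 1 fall and 3 without a call among 7 (adjusted p = 0.468), and their median of 0.07, which turned to -0.02 with median-ratio scaling, lay far under their mean of 0.83. Besides CRA1 the oleosin gene OLEO4 rose by 1.15, the embryo protein gene EM6 was at -0.85 and PER1 was at -0.03. Stomatal lineage genes gave 2 rises, 3 falls and 5 without a call among 10 (adjusted p = 0.275). STOMAGEN was at 0.46, FAMA at -0.82, SPCH at -0.78 and TMM at -0.33. Of 7 reference genes 1 rose, 2 fell and 4 did not pass (adjusted p = 0.275). ACT2 was at -0.28, UBQ10 at -0.26, TIP41 at 0.26, a call that median-ratio scaling ended (adjusted p = 0.164), and PP2AA3 at 0.06. The list's median of 0.05 turned to -0.08 with that scaling, and its mean of -0.035 and its test pointed down.

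Over all genes, 9479 of 18544 passed the test in G34R (51.1%), 6419 higher and 3060 lower, and 922 of the higher and 279 of the lower ones changed at least 2-fold. At 2-fold these were 724 and 378 with median-ratio scaling, and 1504 and 420 with limma-voom and library totals. Every G34R library lay above or below every wild-type library for 10538 genes (56.8%, where chance gives 10%). The median of all genes was 0.10, and median-ratio scaling moved it by -0.12 and made the split 4665 higher and 4911 lower, so the share of higher genes went from 67.7% to 48.7%. Adjusted over the list alone, the counts of higher and lower genes became 8 and 5 for jasmonate, 16 and 3 for abscisic acid, 4 and 21 for photosynthesis, 8 and 3 for iron, 3 and 0 for DNA damage and 0 and 0 for the autonomous pathway, and the other lists kept their counts. With median-ratio scaling the counts of higher and lower genes became 0 and 2 for H3.3, floral repressors and the autonomous pathway, 0 and 0 for Polycomb, 0 and 9 for the morning clock, 2 and 6 for salicylic acid, 6 and 5 for jasmonate and 11 and 3 for abscisic acid. They became 0 and 13 for rapid stress, 8 and 3 for iron, 0 and 8 for flavonoids, 7 and 8 for glucosinolates, 3 and 8 for auxin, 2 and 5 for senescence, 1 and 3 for stomata and 0 and 4 for reference genes. In all, 10 of the 30 tested lists were called, 3 up and 7 down, and 1 with an estimated correlation.

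The comparison of G34W with wild type asked the same of the line with tryptophan. P5CS1, the main enzyme of proline synthesis under stress, went from 133 ± 4.61 to 15.9 ± 0.276 TPM (-2.98 ± 0.05, adjusted p = 9.75e-17), ACS6, an enzyme of ethylene synthesis, from 118 ± 2.999 to 19.2 ± 0.947 TPM (-2.56 ± 0.06, adjusted p = 8.49e-15), and LBD41, a transcription factor gene induced by low oxygen, from 5.78 ± 0.549 to 39.6 ± 2.32 TPM (2.58 ± 0.10, adjusted p = 2.38e-12). MAM3 rose by 2.74, the germin-like gene GLP9 by 2.67, HIS1-3 by 2.61, the zinc transporter gene IRT3 by 2.17, NAS2 by 2.11, PCC1, a defence gene under clock control, by 2.08, and FER1 by 2.08. The other named falls after HTR8 were those of ZAT10 (-2.79 ± 0.16), RLP19 (-2.53 ± 0.13), LEA7, a late embryogenesis protein gene (-2.41 ± 0.18), EXPA8, an expansin gene (-2.40 ± 0.05), and CYS2, a cystatin gene (-2.34 ± 0.11).

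Most root markers rose in G34W too, but only root hair markers passed as a list. All 8 root hair markers rose, with a median of 1.22, which is 1.01 above the median of all tested genes (adjusted p = 0.0128, and adjusted p = 0.144 with an estimated correlation), and 7 of them kept a call with median-ratio scaling. PRP3 rose by 1.34, EXP7 by 1.41, PRP1 by 1.37 and EXP18 by 1.11. Of 8 root endodermis and root tip markers 5 rose, 0 fell and 3 did not pass (adjusted p = 0.0718). CASP1 was at 44.9 ± 1.99 TPM and CASP2, CASP4 and CASP5 up by 0.68, 1.09 and 1.42. Iron deficiency genes gave 4 rises, 6 falls and 3 without a call among 13 (adjusted p = 0.0845): IRT1, FRO2, FIT and F6H1 rose by 1.31, 0.82, 0.59 and 1.44, while the list's median was -0.26. Phosphate starvation genes gave 2 rises, 3 falls and 4 without a call among 9 (adjusted p = 0.332), with a median of -0.07 against a mean of 0.10, PHT1;1 at 1.66, SQD1 at -0.35, MGD2 at -0.62 and SPX1 at -0.26 (adjusted p up to 0.119 without wild type replicate 1 or 3 or G34W replicate 3).

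Most abscisic acid genes and most rapid stress genes fell in G34W. In the abscisic acid, drought and cold list 13 of 21 genes fell, 3 rose and 5 did not pass, with a median of -0.39, and the call held in both forms of the list test (adjusted p = 6.21e-08, and adjusted p = 0.0106 with an estimated correlation). Besides P5CS1 the apoplastic protein gene RD22 went from 344 ± 9.80 to 175 ± 4.596 TPM, RD29B had a change of -1.48, RAB18 of -0.71 and KIN1 of -0.01 (adjusted p = 0.979). Of 17 rapid touch, wound and stress genes 12 fell, 1 rose and 4 did not pass, and this call held as well (adjusted p = 8.48e-09, and adjusted p = 0.0106 with an estimated correlation). ERF104 was at -1.41, SZF1 at -1.16, MPK3 at -1.01 and WRKY40 at -1.62. Salicylic acid genes gave 4 rises, 4 falls and 2 without a call among 10 (adjusted p = 0.0447, 0.0511 without wild type replicate 2, and adjusted p = 0.167 with an estimated correlation). WRKY70 was at -2.04, CBP60G at -1.25, PR5 at -1.24 and EDS1 at -0.16 without a call. Jasmonate genes gave 6 rises, 6 falls and 2 without a call among 14, with a median of 0.01, which became -0.13 with median-ratio scaling, against a mean of -0.09 and a list test that pointed down (adjusted p = 0.0447, 0.0658 without G34W replicate 1, and adjusted p = 0.167 with an estimated correlation). AOC2 had a change of -2.09, AOS of -1.34, AOC1 of -1.25 and VSP1 of 1.02. Heat shock genes gave 3 rises, 3 falls and 3 without a call among 9, and their median of 0.24 and mean of 0.01 were positive while the list test pointed down (adjusted p = 0.333). HSP90.1 was at 1.06, HSP70 at -0.54, MBF1C at 0.24 without a call, and HSFA7A at 0.28, a call lost without G34W replicate 1 (adjusted p = 0.0577) and with median-ratio scaling (adjusted p = 0.528).

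Photosynthesis genes fell and cell division genes rose in G34W. Of 36 photosynthesis genes 29 fell, 2 rose and 5 did not pass, with a median of -0.28 (adjusted p = 5.34e-23, and adjusted p = 0.143 with an estimated correlation). LHCB2.3 had a change of -0.91, LHCB1.4 of -0.77, LHCB2.2 of -0.51 and LHCB2.1 of -0.50, and median-ratio scaling took the median to -0.497 with 34 genes lower and 0 higher (adjusted p = 6.63e-18). Quantile normalization brought it to -0.04 and ended the call (adjusted p = 0.315, the highest over all alternatives, with 7.44e-29 the lowest). Of 24 mitosis and replication genes 23 rose and 1 fell (adjusted p = 0.0186, and adjusted p = 0.167 with an estimated correlation), and 14 rose with median-ratio scaling. CDKB1;1, a kinase gene of mitosis, rose by 0.89, the mitotic activator gene CDC20.2 by 0.82, the replication clamp gene PCNA1 by 0.70 and CDKB2;1 by 0.54. DNA damage genes gave 8 rises, 0 falls and 4 without a call among 12 (adjusted p = 0.314). RAD17 was at 0.81, PARP2 at 0.69, SOG1 at 0.47, whose call quantile normalization ended (adjusted p = 0.0969), and TSO2 at 0.37, whose call median-ratio scaling ended (adjusted p = 0.0985). Of 9 morning clock genes 7 fell, 0 rose and 2 did not pass (adjusted p = 0.000154, and adjusted p = 0.213 with an estimated correlation). CCA1 was at -0.42, LNK1 at -0.38, LHY at -0.22 and LNK2 at -0.06 without a call. Of 5 evening clock genes 3 rose, 0 fell and 2 did not pass (adjusted p = 0.333). TOC1 was at 0.76, LUX at 0.69 and ELF4 at 0.99.

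The 5 H3.1 genes rose in G34W (adjusted p = 0.0017, and adjusted p = 0.143 with an estimated correlation), HTR2 to 201 ± 9.94 TPM, HTR1 from 194 ± 8.22 to 324 ± 19.3 TPM, HTR13 by 0.94 and HTR9 by 0.70. The other chromatin lists passed no list test in G34W. Polycomb genes gave 4 rises, 0 falls and 3 without a call among 7 (adjusted p = 0.481). MSI1 was at 0.49, SWN at 0.45, CLF at 0.33 and EMF2 at 0.24, of which MSI1 and SWN passed with median-ratio scaling. CLF missed the threshold without wild type replicate 2 or 3 or G34W replicate 1 or 3 (adjusted p up to 0.101), and EMF2 without wild type replicate 1 or 2 or any G34W library (adjusted p up to 0.111). H3 chaperone genes gave 3 rises, 0 falls and 5 without a call among 8 (adjusted p = 0.765). ASF1B was at 0.39, HIRA at 0.34 and FAS2 at 0.42, and with median-ratio scaling the list had 0 rises and 1 fall. HIRA missed the threshold without wild type replicate 1 or G34W replicate 2 or 3 (adjusted p up to 0.0834), and FAS2 without wild type replicate 1 or 2 or any G34W library (adjusted p up to 0.219). The H3K36 and H3K4 methylation list gave 2 rises, 0 falls and 10 without a call among 12 (adjusted p = 0.564), with a median of 0.04 that turned to -0.15 with that scaling and a list test that pointed down. There MRG1 was at 0.38, a call that scaling ended (adjusted p = 0.0589), and JMJ30, REF6 and SDG8 were at 0.13, -0.07 and -0.04 without a call. DNA methylation genes gave 2 rises, 0 falls and 4 without a call among 6 (adjusted p = 0.953). DDM1 was at 0.35 and ROS1 at 0.26, neither past the test with median-ratio scaling, and IBM1 at -0.19. DDM1 also missed the threshold without wild type replicate 3 (adjusted p = 0.0749) and ROS1 without wild type replicate 1 or G34W replicate 1 or 2 (adjusted p up to 0.101). The list's median of 0.21 turned to -0.02 with quantile normalization.

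Of the 4 measured floral repressors 2 fell, 0 rose and 2 did not pass in G34W (adjusted p = 0.00775, and adjusted p = 0.167 with an estimated correlation). FLM, a thermosensory repressor gene of the FLC family, went from 14.5 ± 0.890 to 4.89 ± 0.572 TPM (-1.40 ± 0.11), SVP had a change of -0.48 ± 0.06 and MAF2 of -0.02. Of 4 floral promoters 3 rose, 0 fell and 1 did not pass (adjusted p = 0.333), namely FT, SOC1 and SPL3, the latter at 0.26, a call ended by median-ratio scaling (adjusted p = 0.652) and without wild type replicate 1 or G34W replicate 2 or 3 (adjusted p up to 0.145), while SPL4 was at 0.11. SEP3 rose from 1.51 ± 0.369 to 2.66 ± 0.180 TPM (0.55 ± 0.17, adjusted p = 0.0105), a call that median-ratio scaling (adjusted p = 0.056) and the loss of wild type replicate 2 (adjusted p = 0.0521) ended. Autonomous pathway genes gave 3 rises, 0 falls and 3 without a call among 6 (adjusted p = 0.978). LD was at 0.43, FLD at 0.32, FY at 0.27 and FVE at 0.12. With median-ratio scaling the list had 0 rises and 1 fall, and its median of 0.19 turned to -0.01. FLD missed the threshold without G34W replicate 1 (adjusted p = 0.0762) and FY without any single library of wild type or G34W or without G34R replicate 2 (adjusted p up to 0.154).

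Among the remaining lists in G34W, auxin response genes gave 4 rises, 7 falls and 3 without a call among 14 (adjusted p = 0.0157, and adjusted p = 0.143 with an estimated correlation). IAA29 was at -2.29, IAA1 at -0.82, IAA2 at -0.62 and GH3.3 at 1.32. Senescence genes gave 3 rises, 4 falls and 2 without a call among 9 (adjusted p = 0.068). NAP was at -1.53, DIN6 at -0.81, DIN1 at -0.69 and SAG21 at 1.32, and the median of 0.04, against a mean of -0.33, became -0.18 with median-ratio scaling. Flavonoid genes gave 4 rises, 4 falls and 3 without a call among 11 (adjusted p = 0.564). The early genes TT4 and FLS1 were at 0.67 and 0.74 and the late genes DFR and UGT75C1 at -0.92 and -0.70. The median of 0.14, against a mean of -0.09, became -0.07 with that scaling. Glucosinolate genes gave 11 rises, 8 falls and 1 without a call among 20, with a positive median of 0.34 and mean of 0.19 while the list test pointed down (adjusted p = 0.663), and with MYB34 at 0.82, CYP83B1 at 0.70 and MYB28 at -1.15. Seed maturation genes gave 2 rises, 4 falls and 1 without a call among 7 (adjusted p = 0.0718). OLEO4 was at 1.95, CRA1 at 1.88, PER1 at -1.33 and EM6 at -1.32. Stomatal lineage genes gave 0 rises, 2 falls and 8 without a call among 10 (adjusted p = 0.155), with a median of 0.12, which became -0.06 with median-ratio scaling, against a list test that pointed down. There FAMA was at -0.76, STOMAGEN at -0.19 (adjusted p up to 0.0866 without wild type replicate 2 or G34W replicate 2), SPCH at -0.25 and TMM at -0.02. Of 7 reference genes 4 rose, 1 fell and 2 did not pass (adjusted p = 0.897), while 1 rose and 3 fell with median-ratio scaling. TIP41 was at 0.42, ACT2 at -0.16, PP2AA3 at 0.23, a call that median-ratio scaling ended (adjusted p = 0.827), and UBQ10 at 0.19, which turned to -0.03 with that scaling, as the list's median of 0.18 turned to -0.04.

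In G34W 10727 genes passed the test (57.8%), 8300 higher and 2427 lower, with 717 and 322 of them changed at least 2-fold. At 2-fold most genes were lower with median-ratio scaling, 397 higher against 503 lower, so the share of higher genes went from 69% to 44.1%, and limma-voom with library totals gave 1340 and 482. The groups did not overlap for 12082 genes (65.2%, where chance gives 10%). The median of all genes was 0.21, and median-ratio scaling moved it by -0.20 and made the split 4500 higher and 4509 lower, so the share of higher genes went from 77.4% to 50%, and 33 genes were called in the opposite direction. Adjusted over the list alone, the counts of higher and lower genes became 1 and 0 for H3K36 and H3K4 methylation, 2 and 0 for H3 chaperones, 2 and 0 for the autonomous pathway, 5 and 4 for heat shock, 2 and 12 for rapid stress and 2 and 5 for seed maturation, and the other lists kept their counts. With median-ratio scaling they became 0 and 2 for H3.3, 0 and 1 for H3K36 and H3K4 methylation and DNA methylation, 2 and 0 for Polycomb and floral promoters, 0 and 3 for floral repressors, 0 and 0 for the floral organ gene, 0 and 9 for the morning clock, 2 and 5 for salicylic acid and 3 and 16 for abscisic acid. They became 1 and 4 for heat shock, 0 and 13 for rapid stress, 4 and 7 for iron, 2 and 5 for phosphate and seed maturation, 4 and 0 for DNA damage, 2 and 4 for flavonoids, 10 and 8 for glucosinolates, 3 and 7 for auxin, 3 and 5 for senescence and 0 and 4 for stomata. In all, 12 of the 30 tested lists were called, 3 up and 9 down, and 2 with an estimated correlation.

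**Figure D2:**
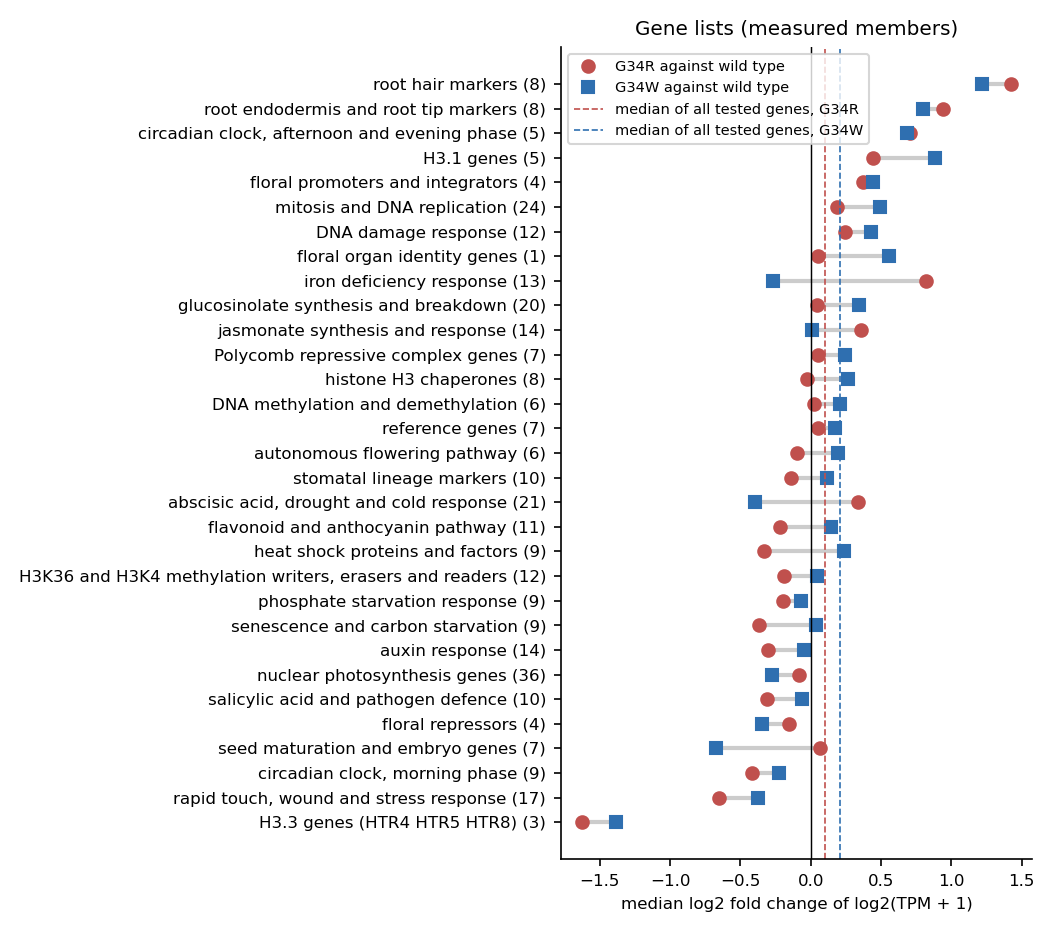
Median log2 fold change (horizontal axis, log2(TPM + 1) scale) of the measured members of each of the 31 gene lists in G34R (circles) and G34W (squares) against wild type, with the number of measured members in parentheses and the medians of all tested genes, 0.10 and 0.21, as dashed lines. Root hair markers lay highest in both lines at 1.42 and 1.22, abscisic acid genes at 0.33 and -0.39, and small medians of several lists change sign when the libraries are scaled by median ratios.

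The comparison of G34W with G34R asked where the 2 lines differ from each other. ICL, the isocitrate lyase of the glyoxylate cycle, was at 34.7 ± 4.59 TPM in G34R and 3.13 ± 0.371 TPM in G34W (-3.11 ± 0.11, adjusted p = 6.01e-12), P5CS1 at 143 ± 5.20 and 15.9 ± 0.276 TPM (-3.09 ± 0.05, adjusted p = 8.33e-17), and ERD5, the proline dehydrogenase gene, at 147 ± 6.48 and 477 ± 9.10 TPM (1.70 ± 0.04, adjusted p = 6.71e-15). GASA6, a gibberellin-regulated peptide gene, had a difference of -2.16 ± 0.05, KIN1 of -2.13 ± 0.24 and CRA1 of -2.13 ± 0.15. Higher in G34W were GAT1_2.1, a glutamine amidotransferase-like gene, by 2.92 ± 0.14, PCC1 by 2.48 ± 0.17, LBD41 by 2.16 ± 0.10 and ESM1, a gene of glucosinolate breakdown, by 1.71 ± 0.05.

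Abscisic acid and iron genes set the lines apart as lists. Of 21 abscisic acid, drought and cold genes 18 were lower in G34W, 0 higher and 3 without a call, with a median of -0.78, and the call held in both forms of the list test (adjusted p = 3.94e-19, and adjusted p = 0.00155 with an estimated correlation). RD22 had a difference of -1.02, RAB18 of -1.15 and RD29B of -0.78. Of 13 iron deficiency genes 10 were lower, 1 higher and 2 without a call, with a median of -0.98, and this call held too (adjusted p = 1.23e-07, and adjusted p = 0.0141 with an estimated correlation). IRT1 was at -1.07, FRO2 at -0.98, FIT at -0.68 and F6H1 at -0.05 without a call. IRT1, FRO2 and FIT act in roots, and root hair markers had a median of -0.309 between the lines. Seed maturation genes gave 1 higher and 6 lower of 7 (adjusted p = 0.000383, and adjusted p = 0.0587 with an estimated correlation). PER1 was at -1.30 and OLEO4 at 0.80. Jasmonate genes gave 1 higher, 6 lower and 7 without a call of 14 (adjusted p = 0.000645, and adjusted p = 0.0831 with an estimated correlation). AOC2 was at -1.66, AOS at -1.09, VSP1 at -0.82 and AOC1 at -0.12 without a call. Photosynthesis genes gave 4 higher, 27 lower and 5 without a call of 36 (adjusted p = 1.81e-13, and adjusted p = 0.261 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.302, the highest over all alternatives, with 2.5e-19 the lowest), and it turned LHCB2.2 from -0.09 to 0.02 and LHCB2.1 from -0.09 to 0. LHCB2.3 was at -0.31 and LHCB1.4 at 0.23.

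Flowering, histone and cell division genes also differed between the lines. Floral repressors gave 0 higher, 3 lower and 1 without a call of 4 (adjusted p = 0.0104, and adjusted p = 0.261 with an estimated correlation). FLM was at -0.94 ± 0.11, SVP at -0.22 (adjusted p up to 0.0551 without G34R replicate 2 or G34W replicate 3) and MAF2 at -0.31 (adjusted p up to 0.0851 without the same libraries). FT was higher in G34W by 1.58 ± 0.21 (adjusted p = 2.83e-05), SPL4 was lower at -0.93, and the floral promoter list gave 2 higher, 1 lower and 1 without a call of 4 (adjusted p = 0.892). The 1 measured floral organ gene, SEP3, was at 0.50, with adjusted p up to 0.115 when any G34W library or G34R replicate 2 or 3 was left out. H3.1 genes gave 4 higher, 0 lower and 1 without a call of 5 (adjusted p = 0.0291, 0.102 without G34R replicate 3, and adjusted p = 0.261 with an estimated correlation). HTR1 was at 0.35 and HTR13 at 0.50. Mitosis and replication genes gave 11 higher, 1 lower and 12 without a call of 24 (adjusted p = 0.0488, 0.102 without G34R replicate 3, and adjusted p = 0.261 with an estimated correlation). PCNA1 was at 0.78 and CDKB2;1 at 0.36. H3.3 genes gave 2 higher, 0 lower and 1 without a call (adjusted p = 0.214). HTR4 was at 0.24, HTR8 at 0.13 without a call and HTR5 at 0.09. The HTR5 value became -0.001 with median-ratio scaling and missed the threshold without G34R replicate 2 or G34W replicate 1 or 3 (adjusted p up to 0.141).

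The remaining lists passed no list test between the lines, and each is given with its genes higher, lower and without a call in G34W. Rapid stress genes gave 7, 2 and 8 (adjusted p = 0.269), with WRKY40 higher by 1.34. Salicylic acid genes gave 3, 1 and 6 (adjusted p = 0.892), with WRKY70 higher by 0.65 and a median of 0.04 that turned to -0.04 with median-ratio scaling. Morning clock genes gave 5, 0 and 4 (adjusted p = 0.165), with LHY at 0.48 and LNK2 at 0.36. With median-ratio scaling 3 were higher and 2 lower, and the calls of CCA1 (adjusted p = 0.0887) and LNK1 (adjusted p = 0.216) ended. Evening clock genes gave 0, 0 and 5 (adjusted p = 0.933), and their test pointed down against a median of 0.035, which turned to -0.042 with that scaling. The counts were 4, 1 and 7 for H3K36 and H3K4 methylation (adjusted p = 0.565), where JMJ30 was at -0.71, and 3, 0 and 4 for Polycomb (adjusted p = 0.224). They were 3, 0 and 5 for H3 chaperones (adjusted p = 0.165) and 2, 0 and 4 for DNA methylation (adjusted p = 0.324). With median-ratio scaling the higher and lower genes of these 4 lists were 0 and 1, 1 and 0, 1 and 0, and 1 and 0, and the calls of REF6 (adjusted p = 0.116), SDG8 (adjusted p = 0.0812) and EMF2 (adjusted p = 0.0551) ended. Auxin genes gave 4, 3 and 7 (adjusted p = 0.892), with GH3.3 at 0.76 and IAA1 at 0.40. Senescence genes gave 4, 4 and 1 (adjusted p = 0.857), with DIN1 at 0.93, NAP at -0.63 and SAG21 at 0.58. The medians of these 2 lists, 0.03 and 0.02, turned to -0.03 and -0.07 with median-ratio scaling. Flavonoid genes gave 4, 1 and 6 (adjusted p = 0.124), with FLS1 at 0.87, TT4 at 0.75 and DFR at -0.56. Glucosinolate genes gave 9, 5 and 6 (adjusted p = 0.892), with CYP83B1 at 0.78 and MYB34 at -0.61. Root hair markers gave 0, 2 and 6 (adjusted p = 0.0601, and 0.0437 without G34R replicate 3), with PRP3 at -0.49. Root endodermis and root tip markers gave 1, 3 and 4 (adjusted p = 0.165), with CASP1 at -0.26 and CASP5 at -0.60. Phosphate genes gave 4, 0 and 5 (adjusted p = 0.124), with SQD1 at 0.36, and DNA damage genes 3, 0 and 9 (adjusted p = 0.196), with TSO2 at 0.44. Heat shock genes gave 1, 1 and 7 (adjusted p = 0.892), with HSFA7A at 0.69 and a median of 0.08 that turned to -0.01 with median-ratio scaling. Stomatal genes gave 2, 1 and 7 (adjusted p = 0.973), with STOMAGEN at -0.65 and SPCH at 0.53. Autonomous pathway genes gave 4, 0 and 2 (adjusted p = 0.165), with FVE at 0.33, and reference genes 3, 0 and 4 (adjusted p = 0.124), with UBQ10 at 0.45.

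Between the lines 6174 genes passed the test (33.3%), 3982 higher and 2192 lower in G34W, with 118 and 132 changed at least 2-fold. At 2-fold these were 99 and 167 with median-ratio scaling, and 212 and 262 with limma-voom and library totals. The groups did not overlap for 8397 genes (45.3%, where chance gives 10%). The median of all genes was 0.07, and median-ratio scaling moved it by -0.08 and made the split 2492 higher and 3250 lower, so the share of higher genes went from 64.5% to 43.4%. Adjusted over the list alone, the counts of higher and lower genes became 5 and 1 for H3K36 and H3K4 methylation, 4 and 0 each for Polycomb, H3 chaperones and reference genes, 4 and 1 for salicylic acid, 4 and 28 for photosynthesis, 2 and 0 for DNA damage, 9 and 6 for glucosinolates and 1 and 4 for root endodermis, and the other lists kept their counts. With median-ratio scaling they became 1 and 0 for H3.3, 3 and 0 for H3.1 and the autonomous pathway, 0 and 0 for the floral organ gene, 2 and 2 for salicylic acid, 1 and 7 for jasmonate, 5 and 2 for rapid stress and 2 and 29 for photosynthesis. They became 2 and 0 for phosphate and DNA damage, 10 and 1 for mitosis, 7 and 7 for glucosinolates, 4 and 4 for auxin, 0 and 3 for root hairs, 1 and 4 for root endodermis and 2 and 1 for reference genes. In all, 8 of 30 lists were called, 2 up and 6 down, and 2 with an estimated correlation.

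The fold changes of the 2 lines were then set side by side. FER1, HIS1-3, MAM3, NAS2, IRT3 and the root hair markers rose in both lines, and HTR8, ZAT10, RLP19, ACS6 and EXPA8 fell in both. Of the genes past the test in each comparison, 7041 changed in the same direction, 5309 higher and 1732 lower, while independent lists of these sizes would share 2873 and 400. Another 310 genes changed in opposite directions. All 310 also passed the test between the lines, which adds no support. The 3 comparisons of a gene share 1 SE, so opposite calls add up to a larger difference. Simulated groups with no change, compared with the same simulated wild-type libraries, shared 0.03 genes on average over 100 draws, and 1 at most. The noise was drawn independently for each gene, so the draws do not measure what the real wild-type libraries contribute. These draws hold no true change, so they do not show how many genes lines with unrelated changes would share. The counts for independent lists leave out that both comparisons use the same wild-type libraries. With median-ratio scaling 3127 genes were higher in both lines, 3221 lower in both and 281 opposite. The changes correlated across genes, which are not independent replicates, with r = 0.77 against a simulated mean of 0.5 and a highest simulated value of 0.523. Their covariance was 0.185 against 0.00784 in the simulation, a difference of 0.178. The 3 wild-type libraries are too few to split, so part of the shared calls may come from these shared controls.

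**Figure D3:**
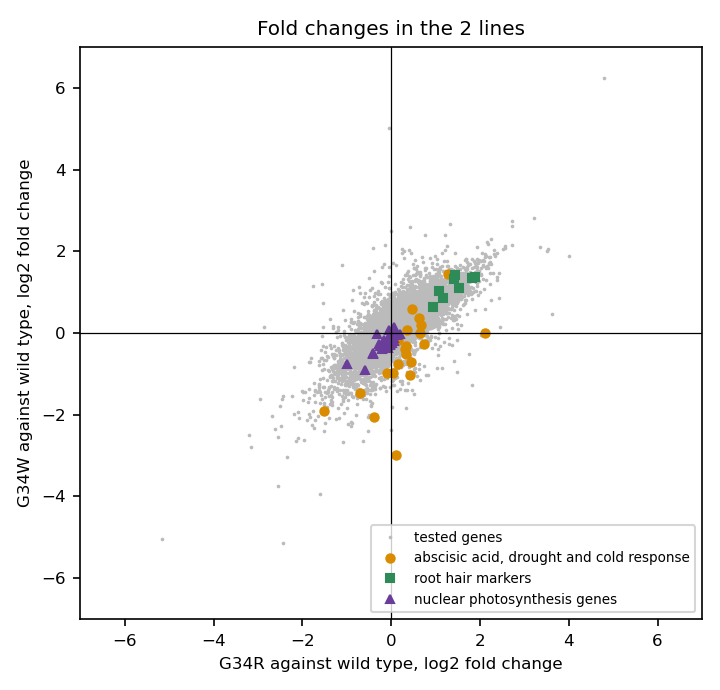
Log2 fold changes (log2(TPM + 1) scale) of the 18544 tested genes in G34R (horizontal axis) and G34W (vertical axis) against wild type, with the measured members of 3 gene lists coloured. All 8 root hair markers lay in the upper right, the photosynthesis genes near the centre, their medians at -0.08 and -0.28 and the G34R median at 0.02 with quantile normalization, and the abscisic acid genes mostly below the diagonal.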

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

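The tests of TPM scaling, of both explanations for the genes beside HTR5 and of the time of day were chosen after the results were seen, and the tests on added root genes, reserve genes, gene span, expression level and other splits before. Between the lines, the following had opposite directions against wild type and passed the test of the difference, and groups of 3 were not tested for outlying samples. For the genes, which were called in opposite directions against wild type, passing that test follows from the shared SE and is no further support. The log2 difference between G34W and G34R was 2.922 for GAT1_2.1, 1.71 for ESM1, 1.697 for ERD5 and 0.687 for HSFA7A, and median-ratio scaling ended the calls of ESM1 (0.339 to 0.12, adjusted p = 0.0934) and HSFA7A (0.281 to 0.068, adjusted p = 0.528) in G34W against wild type. It was -3.11 for ICL, -2.158 for GASA6, -1.154 for RAB18 and -0.652 for STOMAGEN, whose call in G34W against wild type limma-voom with library totals ended (adjusted p = 0.0526). As list medians it was -0.78 for abscisic acid, drought and cold genes and -0.983 for iron deficiency genes. Against wild type, the list test called the iron list in neither line (adjusted p = 0.181 in G34R and 0.0845 in G34W). It called the abscisic acid list in G34W but not in G34R (adjusted p = 0.0628), so these opposite directions are of medians only.

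Most root markers were higher in both lines. The root endodermis and root tip list did not pass the list test in G34W (adjusted p = 0.0718). No call of a root list held with an estimated correlation. Scaling of the TPM was argued against, since the lowest median of the root hair and root endodermis lists in either line was 0.567 with median-ratio scaling or quantile normalization. A larger share of root tissue stayed open, and the added root genes met the bound set for it beforehand. In both lines, 23 further root-expressed genes had medians at least 0.515 above the median of all genes. Of these 20 were higher and 3 lower in G34R (adjusted p = 6.3e-06, and 0.126 with an estimated correlation), 19 and 3 in G34W (adjusted p = 0.00215, and 0.167 with an estimated correlation), and 2 and 12 between the lines (adjusted p = 7.97e-05, and 0.174 with an estimated correlation). A larger root share would also lower photosynthesis genes, whose medians were -0.08 in G34R and -0.28 in G34W, -0.214 and -0.497 with median-ratio scaling and 0.02 and -0.04 with quantile normalization, and an effect on root genes without a change in tissue share was not tested.

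The gene next to HTR5 on its promoter side in the TAIR10.1 annotation, AT4G40042, was at 21.8 ± 2.17 TPM in wild type, 51.9 ± 2.78 TPM in G34R and 118 ± 9.16 TPM in G34W. Of the genes after it, all chosen after their values were seen, AT4G40045 was at 44.0, 33.3 and 127 TPM and AT4G40050 at 26.6, 28.8 and 29.2 TPM. Further out, AT4G40063 rose by 1.166 and 0.899 and AT4G40070 by 0.893 and 1.054 in G34R and G34W, so rises were not limited to the nearest genes. The TPM that AT4G40042 gained in G34W beyond the gain of HTR5, 49.8, does not decide on reads running on from HTR5, since this gene lies on the promoter side. An added gene fragment reaching these neighbours and a change of the chromosomal genes cannot be told apart, since AT4G40042 rose by at least 1.218 in both lines and reads of such copies are identical.

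Abscisic acid, drought and cold genes were lower in G34W than in G34R, with a median of -0.78. A large shift in the time of harvest was argued against as the whole cause, since the median absolute clock gene difference was 0.148. Of 9 morning clock genes 5 were higher in G34W and 0 lower, or 3 and 2 with median-ratio scaling. A smaller shift stayed open, since the swing of the abscisic acid genes over the day was not measured. The clock values here cover the difference between the lines only. Against wild type, where the called morning clock genes fell and the called evening ones rose, time of day was not tested. Delayed seedling establishment in G34R cannot be told apart from other causes: the median of 12 genes of reserve use was -0.126, between the bounds set for and against it. Of these genes 10 were higher in G34R than in wild type and 0 lower, 8 and 1 in G34W, and 0 and 5 between the lines (adjusted p = 0.00049, and adjusted p = 0.13 with an estimated correlation). A direct effect of the substitutions was not tested.

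Across genes, the rank correlation of fold change with gene span was -0.193 in G34R, -0.086 in G34W and 0.203 between the lines, and with expression level -0.09, -0.112 and -0.018. The 10 splits of 6 libraries are too few for a share under 0.05. The 1 real split gave 9479, 10727 and 6174 changed genes in the 3 comparisons, and the highest other split 0. It gave 10, 12 and 8 called lists, and the highest other split 6, 10 and 6. Of 100 splits of the 9 libraries, 1, the real one, reached the overlap of 7041 genes, with 5721 the highest other. The other splits mix the real groups. This keeps group differences in them and widens the spread within groups, so they cannot decide on chance. For the correlation of fold changes, 30 of 100 splits reached r = 0.77, with 0.937 the highest other. Mixed splits can keep a shared difference from wild type in both comparisons, so this share does not decide on chance either. Simulated groups with no change had a mean r of 0.5 and at most 0.523.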

How the results depend on the processing

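The limma-voom fits were chosen after seeing the data and used reads recovered from the TPM, and the planned edgeR fit was not run because the table holds TPM and not raw counts. Among the counts of genes at any fold size, those named here moved by over 1.5 times, and the cause was not tested unless stated. Scaling shifts all genes by construction. With median-ratio scaling, quantile normalization and limma-voom with median-ratio sizes in turn, G34R had 4911, 4961 and 5107 lower genes, and G34W 4500, 4617 and 4535 higher and 4509, 4224 and 4631 lower. Genes higher in both lines were 3127, 3134 and 3076, and lower in both 3221, 2992 and 3401. Between the lines 2492 genes were higher with median-ratio scaling and 3457 lower with limma-voom and median-ratio sizes. At 2-fold, which keeps fewer genes by construction, 1201 genes changed in G34R (922 higher, 279 lower), 1039 in G34W (717 and 322), 250 between the lines (118 and 132) and 602 in both lines (459 and 143). These 2-fold counts moved by over 1.5 times in G34W with median-ratio scaling (397 and 503), and with limma-voom and library totals in all 3 comparisons, to 1924, 1822 and 474 genes. The correlation of fold changes was 0.783 at 5 TPM and 0.761 with array quality weights, and 0.759 without G34R replicate 3 to 0.777 without wild type replicate 2.

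With an estimated correlation 1, 2 and 2 lists were called in the 3 comparisons, and at 5 TPM 6 in G34R. The list test with an estimated correlation ended the calls below. The estimate lay under the preset 0.01 for auxin (-0.009), senescence (-0.086), root endodermis (-0.05), salicylic acid (-0.014) and seed maturation (-0.147). For these lists a higher correlation did not end the call, and what did was not tested. The estimates of the other lists below lay above 0.01, from 0.017 for root hairs to 0.591 for the morning clock. In G34R the adjusted p became 0.174 for H3.3 and flavonoids, 0.166 for H3.1, auxin and senescence, 0.238 for the morning clock, 0.289 for photosynthesis, 0.138 for root hairs and 0.173 for root endodermis. In G34W it became 0.167 for H3.3, floral repressors, salicylic acid, jasmonate and mitosis, 0.143 for H3.1, photosynthesis and auxin, 0.213 for the morning clock and 0.144 for root hairs. Between the lines it became 0.261 for H3.1, floral repressors, photosynthesis and mitosis, 0.0831 for jasmonate and 0.0587 for seed maturation.

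Other settings ended or made list calls. At 5 TPM, where fewer genes are tested, adjusted p in G34R was 0.109 for flavonoids and senescence, 0.0565 for auxin and 0.144 for root endodermis, and in G34W 0.143 for salicylic acid, 0.0854 for mitosis and root hairs and 0.215 for auxin. Without a filter it was 0.0165 for floral repressors and 0.0441 for phosphate in G34R, and 0.366 for salicylic acid and 0.0799 for jasmonate in G34W. With median-ratio scaling it was 0.0723 for auxin in G34R, 0.166 for salicylic acid, 0.229 for jasmonate and 0.155 for auxin in G34W, and 0.0743 for H3.1 between the lines. With quantile normalization it was 0.0479 for abscisic acid, 0.0567 for auxin, 0.071 for senescence and 0.8 for photosynthesis, whose direction turned, in G34R. There it was 0.104 for salicylic acid and auxin, 0.206 for jasmonate and 0.315 for photosynthesis in G34W, and 0.302 for photosynthesis and 0.0214 for reference genes between the lines. With limma-voom and median-ratio sizes it was 0.055 for flavonoids and 0.0714 for auxin in G34R, 0.126 for salicylic acid, jasmonate and auxin in G34W, and 0.0995 for H3.1 between the lines. With limma-voom and library totals it was 0.0674 for root endodermis in G34R and 0.0982 for H3.1 between the lines. Between the lines array quality weights gave 0.0595 for H3.1, 0.115 for mitosis and 0.0266 for root hairs, and leaving out organelle genes gave 0.0506 for mitosis. In G34W pseudocount 0.1 gave 0.0512 for salicylic acid. Robust moderation changed none of 90 list results.

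Replicate numbers did not pair the libraries, with correlations of -0.023 to 0.041 for the 9 pairs of one number and -0.059 to 0.029 for the others. A replicate block changed no count by over 1.5 times, and adjusted p became 0.0502 for jasmonate in G34W and 0.0574 for mitosis between the lines.

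With each library left out, adjusted p in G34R ran from 0.0431 without G34R replicate 1 to 0.0717 for salicylic acid and from 0.0486 without G34R replicate 3 to 0.0977 for abscisic acid. In G34W it ran from 0.0383 to 0.0511 without wild type replicate 2 for salicylic acid and from 0.0279 to 0.0658 without G34W replicate 1 for jasmonate. Between the lines it ran, with the highest values of H3.1 and mitosis and the lowest of root hairs without G34R replicate 3, from 0.0145 to 0.102 for H3.1, from 0.0286 to 0.102 for mitosis and from 0.0437 to 0.125 for root hairs.

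Of 343 calls of named genes 42 were lost without at least 1 library, all of them changes of 0.553 or less in size, and 6 reversed under a scaling. HTR5 turned to -0.032 in G34R, -0.033 in G34W and -0.001 between the lines with median-ratio scaling, and to -0.028, -0.029 and -0.002 with limma-voom and median-ratio sizes. UBQ10 turned to -0.03 and -0.027 in G34W with these, and between the lines LHCB2.2 turned to 0.017 and LHCB2.1 to 0 with quantile normalization. Median-ratio scaling kept 370 of 423 named results, ended 33 calls and made 16, while quantile normalization ended 30 and limma-voom with median-ratio sizes 33. Pseudocount 0.1, which by construction widens the changes of weak genes, enlarged the falls of FLC in all 3 comparisons. Depth limits weak genes, since 3 reads in a gene of 1 kb are 0.422 to 0.495 TPM.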

Other observations

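No test of an explanation is given in this part, and its gene groups and genes were chosen after their values were seen. Genes grouped by product name, with 172 names of at least 10 genes and 344 tests a comparison by Fisher's exact test, were tested for genes at least 2-fold higher or lower. Peroxidases, many of which act on cell walls, had 25 of 40 genes higher in G34R (62.5%, against 4.87% of other genes, adjusted p = 1.42e-20) and 17 of 40 in G34W (adjusted p = 1.11e-11). With median-ratio scaling 20 and 12 of them were. Lipid-transfer and 2S albumin-like proteins had 21 of 42 genes higher in G34R (adjusted p = 1.27e-14) and 14 of 42 in G34W (adjusted p = 5.08e-08), and 19 and 7 with that scaling. Dirigent-like proteins, which guide lignan and lignin formation, had 11 of 18 (adjusted p = 1.2e-08) and 8 of 18 (adjusted p = 1.75e-05), and 10 and 4 with that scaling. Histone genes had 6 of 27 (adjusted p = 0.0393) and 8 of 27 (adjusted p = 0.00039), and 4 and 3 with that scaling. Berberine bridge enzyme-like genes had 7 of 15 higher in G34W (adjusted p = 5.4e-05) and 3 of 15 higher in G34W than in G34R (adjusted p = 0.0367), and 5 and 3 with that scaling. At least 2-fold lower in G34R were 7 of 53 SAUR auxin-response genes (adjusted p = 0.00106) and 5 of 41 integrase-type DNA-binding genes (adjusted p = 0.0142), and 8 and 7 with that scaling. Root hair markers, root endodermis and root tip markers and the added root genes had medians of 1.421, 0.94 and 0.927 in G34R and 1.215, 0.796 and 0.721 in G34W in the same libraries.

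Some genes without a symbol differed by more than most. AT5G23115 was listed at 0 in the 3 wild-type libraries and was at 26.8 ± 3.45 TPM in G34R and 76.3 ± 21.1 TPM in G34W. AT1G53200 was at 5.53 ± 0.313, 5.32 ± 0.520 and 209.7 ± 5.67 TPM in wild type, G34R and G34W. AT3G44970 was at 38.3 ± 1.57, 6.23 ± 0.747 and 0.126 ± 0.0815 TPM, AT1G75945 at 29.6 ± 1.11, 3.24 ± 0.776 and 32.7 ± 2.46 TPM, and AT1G68250 at 0.318 ± 0.286, 15.04 ± 2.55 and 0.945 ± 0.828 TPM.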
